A study of Mus musculus with 62 samples.

How the data were processed

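RNA from blood and spleen of naive male mice was profiled on Illumina MouseRef-8 bead arrays, with 62 arrays from 3 experiments, 2 tissues and 2 genotypes (the BQ strain and its Ncf1 m1J mutant). Per the labels, RNA was depleted of globin transcripts in all samples and 250 ng was labelled. Per the labels, other isolation kits were used in experiment II than in experiment I, for both tissues, so kit and experiment coincide. Per the submitters' processing notes limma was used, with no version and no design given.

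A deposited table of non-normalized values holds 1 intensity per probe and array for 25697 probes; the values are linear, above 0 and differ in distribution between arrays, so no normalization was found in them, and the table has no detection p values and no control probes. A deposited matrix holds normalized intensity values on the linear scale for the arrays of experiments I and II, which the authors quantile normalized within each tissue, as read from the sorted values of the arrays, which lay within 0.343% of the median of their rank. The same deposited matrix holds log2 values for the germ-free arrays, which the authors quantile normalized within each tissue over the germ-free arrays alone. Ranks within each array were the same in the matrix and in the non-normalized table (lowest Spearman r 1). The matrix was used only as an alternative, after its linear part had been brought to log2. No arrays held identical values, and 0 columns lacked a sample.

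All values reported start from the non-normalized intensities. They were background corrected with normexp at an offset of 50, brought to log2 and quantile normalized within each tissue over all of its arrays. For the comparison of tissues the arrays of experiments I and II were normalized together. Since no detection p was given, the filter kept the upper 50% of probes by mean log2. Gene names came from the platform's probe table, in which 23978 probes name 1 gene, 0 probes several and 1719 none. Probes without a gene name were left out. Names were checked against the RefSeq annotation of GRCm38.p6 by gene identifier, which matched 23962 probes and renamed 0; that annotation was used for names and gene positions. Each gene was represented by its probe of highest mean, out of 16593 gene symbols on the array. Where the Ncf1 probes lie relative to the mutation was not known.

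Linear models were fitted with limma 3.58.1 in R 4.3.3, 1 fit per tissue with a mean for each genotype in each experiment, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The genotype difference of experiments I and II is the mean of the differences in each, so that the experiment is a block. Each fit shares 1 estimate of the spread per gene over all of its arrays, whatever their experiment. Further contrasts were the germ-free difference, the single experiments, the genotype by experiment, germ-free state and tissue interactions, and germ-free against conventional wild type spleen. Samples were grouped by the labels. Blood and spleen samples of an experiment share numbers in their titles, but the labels do not say that a number is an animal, so tissues were not paired. All tests are 2-sided. Germ-free blood, with 1 wild type array, is given as values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. On simulated data with the same design, 200 genes were changed and noise was drawn for each gene on its own. Folds of 1.5, 2 and 4 were recovered in 76.1, 94 and 100% of changed genes in blood of experiments I and II. The shares were 91, 100 and 100% in spleen of these experiments and 64.2, 92.5 and 100% in germ-free spleen. The real arrays also differ in ways shared by many genes, so recovery there may be lower.

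Gene lists were written from general knowledge: type I interferon response, interferon gamma response, phagocyte oxidase complex, antioxidant genes, inflammatory cytokines and NF-kB targets, markers of neutrophils, monocytes and macrophages, dendritic cells, B cells, plasma cells, T cells, NK cells, platelets and erythroid cells, globin genes, cell cycle, immediate early and heat shock genes, exocrine pancreas genes, ribosomal proteins and genes near Ncf1 on chromosome 5. The type I interferon list was chosen with published work on Ncf1 mutant mice in mind, which reports an interferon signature. These 20 lists hold 388 entries, 333 of them with a named probe, and 9 to 41 genes each. They were tested with camera from limma at a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the 20 lists. Fry tests whether the genes of a list move, on balance, 1 way, and does not compare them with other genes. Per-array list means were compared by permutation within experiments, with 100000 draws for experiments I and II together and by exact enumeration elsewhere. A list of liver genes was added after the data were seen.

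The genes named were set by a rule. It took Ncf1 in every comparison; the 12 higher and 12 lower genes of largest difference among those past the threshold with the same sign in experiments I and II, for blood and for spleen; 5 higher and 5 lower past the threshold for other comparisons; the 4 members of smallest p of each list; and the 5 genes of smallest p where fewer than 3 passed. Symbols that are only predicted or clone identifiers were passed over. Outside the rule, Gvin1 in conventional spleen, the germ-free values of Ltf, Ctsg, Cd27 and Oasl2 and the genes given for germ-free blood were chosen after their values were seen. The groups, lists, models, naming rule and first set of other settings were fixed before the data were examined.

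The settings chosen beforehand were no background correction, median centring, both tissues normalized together, each experiment normalized on its own, the deposited matrix, no filter, all probes, a trended and robust variance, array weights, only the arrays compared, leaving out each array, the number block for the tissue comparison, and other list tests. Added after the data were seen were the range of the title number as a block, a liver gene covariate, leaving out the blood arrays of experiment I or 3 spleen arrays with pancreas genes (the latter also with other list tests), a filter at the upper 25% of probes, and, for the tissue comparison, lists without members that did not pass the filter in blood. The number of arrays limits the precision of the differences.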

Results

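Transcript levels were measured with Illumina bead arrays in blood and in whole spleen of naive male mice of the BQ strain. The mice carried either the wild type Ncf1 gene or the mutant allele Ncf1 m1J, and their cells were not cultured or stimulated. Ncf1 encodes a cytosolic subunit of the phagocyte NADPH oxidase, the enzyme complex with which neutrophils and macrophages make superoxide. The 62 arrays came from 3 experiments. Experiments I and II each held 6 mutant and 6 wild type arrays of blood and the same numbers of spleen. A germ-free experiment held 6 mutant and 5 wild type spleen arrays, with 2 mutant and 1 wild type blood arrays. The 75th percentile of the raw intensity was 1.64 to 3.06 times the 5th percentile of the same array in blood and 2.52 to 6.39 times in spleen. The number of arrays limits the precision of every difference. Differences are mutant minus wild type on the log2 scale with the standard error (SE) of the fit, and counts of arrays are mutant arrays on the stated side of the wild type mean of their own experiment.

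Ncf1 itself was measured first, since it is the gene that carries the mutation. It lies on chromosome 5 (134220053 to 134229628, GRCm38.p6), and the probe that passed the filter was ILMN_2829457. In spleen of experiments I and II together, Ncf1 fell by 0.80 ± 0.11 SE in mutants (adjusted p = 4.5e-05, lower in 12 of 12 mutant arrays). In germ-free spleen it fell by 0.92 ± 0.16 SE (1.89-fold lower, adjusted p = 0.017, lower in 6 of 6). In blood of experiments I and II it was lower in 12 of 12 mutant arrays (adjusted p = 0.019). Mean levels in wild type spleen were 7.23 ± 0.35 (SD, n = 6) in experiment I, 7.45 ± 0.16 (SD, n = 6) in experiment II and 8.36 ± 0.29 (SD, n = 5) in germ-free mice. The matching mutant means were 6.31 ± 0.31, 6.76 ± 0.14 and 7.44 ± 0.31 (SD, n = 6 each). In blood the wild type and mutant means were 6.37 ± 0.34 and 5.98 ± 0.10 in experiment I, and 7.09 ± 0.18 and 6.48 ± 0.16 in experiment II (SD, n = 6 each). The genotypes did not overlap in spleen of experiments I and II or in blood of experiment II, but they did in blood of experiment I and in germ-free spleen, where the lowest wild type array read 7.89 and the highest mutant array 7.98. The second Ncf1 probe, ILMN_1228585, read 5.86 to 5.98 in every group mean and did not pass the filter. The mutant blood mean of experiment I, with arrays from 5.81 to 6.09, lay at that level, as did mutant spleen replicates 27 and 28 of experiment I (both 5.97), so the fitted differences of experiments I and II, -0.50 ± 0.093 SE in blood and -0.80 in spleen, may understate the fall and no fold is given for them. The Ncf1 calls in blood and germ-free spleen were lost with median centring in place of quantile normalization (adjusted p = 0.52 and 0.095). The germ-free call was also lost with only the arrays compared in the fit (adjusted p = 0.57, or 0.30 with the range of the title numbers as a block). It was lost too without the arrays that carry pancreas genes (adjusted p = 1). Over the other settings the germ-free difference itself stayed between -0.98 and -0.79. The blood call was also lost without wild type replicate 7 (adjusted p = 0.051) or mutant replicate 33 (adjusted p = 0.0505) of experiment II, and the germ-free call when wild type GF-S1, GF-S461, GF-S463 or GF-S1141 or mutant GF-S3, GF-S504 or GF-S1143 was left out, with an adjusted p of up to 0.15 without GF-S1141.

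**Figure D1:**
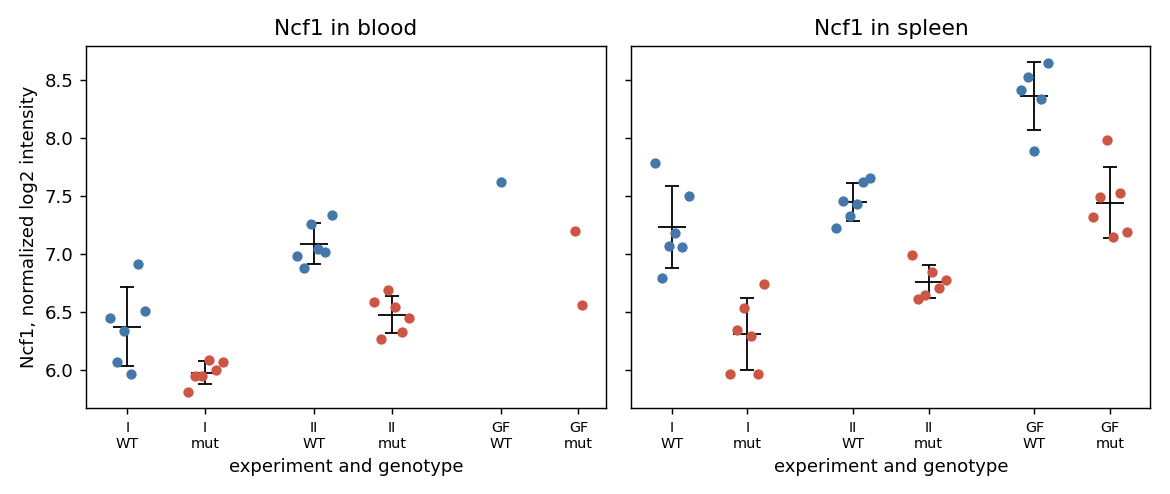
Ncf1 on each array (normalized log2 intensity, vertical axis) by experiment and genotype (WT, wild type; mut, mutant; GF, germ-free), with blood on the left and spleen on the right. Points are arrays and black lines the mean ± SD of groups of 5 or 6; mutant means lie below wild type means in every pair, by 0.92 in germ-free spleen.

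The comparison of mutant with wild type blood asked which transcripts differ with the Ncf1 genotype in unstimulated mice. Interferon-inducible genes rose in mutant blood of experiments I and II. Gvin1, a giant interferon-inducible GTPase, was 3.42-fold higher (log2 difference 1.77 ± 0.16 SE, adjusted p = 8.3e-07, higher in 12 of 12 arrays). Oasl2, of the oligoadenylate synthetase family of antiviral proteins, was 2.12-fold higher (1.09 ± 0.17 SE, adjusted p = 0.0044, 12 of 12). Irgm2, an immunity-related GTPase, was 1.84-fold higher (0.88 ± 0.13 SE, adjusted p = 0.0030, 12 of 12), and Cxcl9, a chemokine induced by interferon gamma, rose by 0.66 ± 0.12 SE (adjusted p = 0.019, 12 of 12) from a low wild type level (6.19 in experiment II). Ffar2, a receptor for short-chain fatty acids, rose by 0.65 ± 0.11 SE (adjusted p = 0.0057, 9 of 12). Its rise was 1.16 in experiment II, in 6 of 6 arrays, so the mean of both experiments rests mostly on that one. The adenylate cyclase gene Adcy4 rose by 0.32 ± 0.057 SE (adjusted p = 0.014, 11 of 12). Tdrp fell by 0.58 ± 0.096 SE (adjusted p = 0.0057, 12 of 12).

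These genes and Ncf1 made up the 8 genes that passed limma's test among 9075 in blood, 6 higher and 2 lower. At an unadjusted p under 0.05 there were 496 genes, where chance gives 453.75. The mean of 16 liver genes, a list chosen after the data were seen, moved with experiment I. It read 6.91 to 8.996 on the 6 mutant blood arrays of experiment I and 5.99 to 8.69 on the wild type ones, against 5.89 to 5.995 on the other blood arrays. With the liver gene mean as a covariate 27 genes passed, and 29 passed in experiment II alone, where Oasl2 did not (adjusted p = 0.071). The count was 58 with array weights, 13 with all probes or without wild type replicate 30 of experiment I, and 4 with the upper 25% of probes, while Irgm2, Tdrp and Ncf1 were lost with median centring, and Cxcl9 without mutant replicate 6 of experiment I (adjusted p = 0.053) or wild type replicate 7 of experiment II (adjusted p = 0.051).

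**Figure D2:**
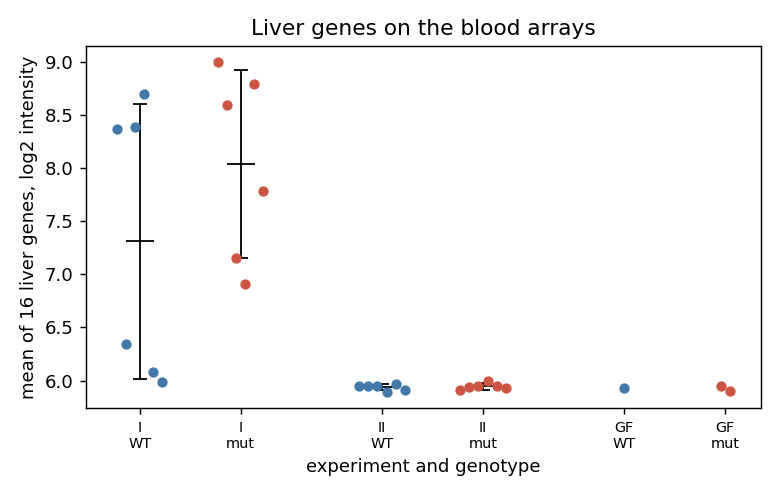
Mean of 16 liver genes (log2 intensity, vertical axis) on each blood array, by experiment and genotype (WT, wild type; mut, mutant; GF, germ-free). Points are arrays and black lines the mean ± SD of groups of 6; all arrays outside experiment I lie between 5.89 and 5.995.

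Among the gene lists in blood, the interferon gamma response list moved most. All 16 of its measured members were higher in mutants, by 0.43 on average, and its per-array mean was higher in 9 of 12 mutant arrays, 3 of 6 in experiment I and 6 of 6 in experiment II. Over all genes 2 members passed, Irgm2 and Cxcl9, and 9 passed when adjusted over the list alone; Gbp2, a guanylate-binding protein, read 1.18 ± 0.26 SE (adjusted p = 0.12). The list passed camera (adjusted p = 1.2e-16, adjusted p = 0.043 with an estimated correlation) and had a permutation p of 0.0043 before and 0.086 after adjustment over 20 lists, so it did not pass that test. Of the 30 measured members of the type I interferon list, 26 were higher, with a mean of 0.20; Oasl2 passed over all genes and 4 members when adjusted over the list alone. Its per-array mean was higher in 8 of 12 mutant arrays, 3 of 6 in experiment I and 5 of 6 in experiment II. This list passed camera (adjusted p = 2.6e-10), but had an adjusted p = 0.20 with an estimated correlation and a permutation p of 0.019 before and 0.14 after adjustment over 20 lists. Ifitm3 (0.64 ± 0.15 SE, adjusted p = 0.18) and Oas1g (0.50 ± 0.12 SE, adjusted p = 0.19) were higher in 12 of 12 arrays without passing.

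Of the cell type lists in blood, 3 passed camera. T cell markers averaged -0.33, with 0 of 14 members past limma's threshold over all genes and 5 lower when adjusted over the list alone, and the list was lower in 10 of 12 arrays. Camera gave adjusted p = 3.2e-07 for it, and the call was lost, with adjusted p = 0.36 with an estimated correlation. Over 19 other settings the mean of this list ran from -0.40 to -0.15, with the call kept in 17. Il7r, the receptor chain for interleukin 7, read -0.62 ± 0.15 SE (adjusted p = 0.19), and Cd8b1, a chain of the co-receptor of cytotoxic T cells, read -0.64 ± 0.19 SE (adjusted p = 0.39). Neutrophil markers averaged 0.21, with 1 member higher when adjusted over the list alone, and erythroid markers -0.15, with 0 such members. Their camera adjusted p of 0.012 and 0.019 became adjusted p = 0.60 with an estimated correlation for both. The other 15 lists did not pass, with camera adjusted p from 0.066 for the exocrine pancreas genes to 0.90 for the NK cell markers. With fry, only the interferon gamma list passed in blood (adjusted p = 0.023).

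The same comparison in spleen of experiments I and II showed a larger set of changes. Genes of neutrophil granules rose most. Ltf, the iron-binding protein lactoferrin, was 2.72-fold higher in mutants (1.45 ± 0.32 SE, adjusted p = 0.018), the serine protease Ctsg 2.63-fold (1.40 ± 0.22 SE, adjusted p = 4.4e-04), and Mpo, the myeloperoxidase of the granules formed first, 2.49-fold (1.32 ± 0.31 SE, adjusted p = 0.031), each in 12 of 12 arrays. Lcn2 (1.36), Prtn3 (1.36), Ngp (1.34), Camp (1.08) and Cebpe (0.80), a transcription factor of granulocyte maturation, rose as well, with adjusted p from 0.015 to 0.045. Ms4a3, a marker of granulocyte and monocyte progenitors, rose by 0.92 ± 0.14 SE (adjusted p = 2.0e-04), the activating antibody receptor Fcgr4 by 0.81 ± 0.12 SE (adjusted p = 1.8e-04) and the formyl peptide receptor Fpr2 by 0.78 ± 0.16 SE (adjusted p = 0.013).

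T cell genes fell in the same spleens. Cd8b1 showed the smallest p of all genes tested there and was 1.89-fold lower (fell by 0.92 ± 0.091 SE, adjusted p = 8.5e-08, lower in 12 of 12 arrays, with no overlap of the genotypes in either experiment). Cd27, a co-stimulatory receptor of lymphocytes, fell by 0.57 ± 0.078 SE (adjusted p = 4.5e-05), Cd3e, a chain of the T cell receptor complex, by 0.44 ± 0.089 SE (adjusted p = 0.0090) and Cd5 by 0.36 ± 0.082 SE (adjusted p = 0.030). Klrd1, a receptor of NK and cytotoxic T cells, fell by 0.43 (adjusted p = 0.021). Cd209b, a lectin of marginal zone macrophages, fell by 0.69 (adjusted p = 0.045), and Cox6a2 by 0.54 (adjusted p = 0.017). Klk8, Klk1b27, Ahnak and Sidt1 fell by 0.40 to 0.46, with adjusted p from 0.0024 to 0.017. Tdrp fell here as in blood, by 0.45 ± 0.068 SE (adjusted p = 2.0e-04).

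Interferon-inducible genes also rose in mutant spleen. The guanylate-binding protein gene Gbp2b rose by 0.98 ± 0.16 SE (adjusted p = 3.7e-04), Oasl2 by 0.76 ± 0.18 SE (adjusted p = 0.030), Gvin1 by 0.72 ± 0.12 SE (adjusted p = 5.0e-04), Gbp2 by 0.68 ± 0.15 SE (adjusted p = 0.020), the immunity-related GTPase gene Igtp by 0.58 ± 0.11 SE (adjusted p = 0.0041), the peptide transporter gene Tap1 by 0.47 ± 0.10 SE (adjusted p = 0.015) and Irgm2 by 0.45 ± 0.11 SE (adjusted p = 0.042). Each was higher in 11 or 12 of the 12 mutant arrays. Blood and spleen shared 6 called genes, Irgm2, Ffar2, Tdrp, Ncf1, Oasl2 and Gvin1, each with the same sign, of the 8069 genes tested in both. The tissues may come from the same animals, so calls in both are not independent.

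In all, 55 of 8968 genes passed limma's test in spleen of experiments I and II, 31 higher and 24 lower, with fold changes of 1.17 to 2.72. At an unadjusted p under 0.05 there were 708 genes, where chance gives 448.4. Across the genes tested, which are not independent replicates, the differences of the experiments correlated with r = 0.458 and rho = 0.25. Of the 525 genes at an unadjusted p under 0.05 in experiment I, 74.7% had the same sign in experiment II. Exocrine pancreas genes averaged 10.68 on wild type replicate 7 of experiment I, against 6.26 to 6.90 on all but 3 spleen arrays. Without those 3 arrays 41 genes passed, and Lcn2, Camp, Cebpe, Oasl2 and Cd5 did not. Over all other settings Lcn2 stayed at 1.31 or more, Camp at 1.02 or more and Cebpe at 0.65 or more. Oasl2 fell to 0.49 at the lowest, and Cd5 shrank to -0.21. In spleen of experiment I, arrays with title numbers up to 20 differed from those above in 5022 genes, with 3 mutants and 3 wild types in each range, and 207 genes passed with the range as a block, among them all 55. The count was 20 (9 higher, 11 lower) with median centring, 36 without wild type replicate 39 of experiment II, 33 with the upper 25% of probes and 3182 with array weights. In experiment I these weights were 0.148 to 0.235 for wild type replicates 1, 5 and 7 and mutant replicates 25, 27 and 28. The other spleen arrays of experiment I had 0.905 to 3.04. The weighted fit thus set mostly high-number wild types against low-number mutants there, so the 3182 genes cannot be told apart from the number range. When each of the 35 spleen arrays was left out in turn, Cd209b kept its call in 12 fits, Camp in 13, Irgm2 in 19, Lcn2 in 22, Cebpe in 23, Mpo in 25, Oasl2 in 27, Cd5 in 29 and Gbp2 and Klrd1 in 34. Median centring ended the calls of Ltf, Lcn2, Prtn3, Ngp, Mpo, Camp, Cebpe, Fpr2, Cd209b, Klk8, Klrd1, Klk1b27, Sidt1, Cd5 and the interferon-inducible Oasl2, Igtp, Tap1, Gbp2 and Irgm2, and only the arrays compared in the fit those of Cd209b, Cox6a2, Klk8, Klrd1, Gbp2, Irgm2 and Cd5.

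**Figure D3:**
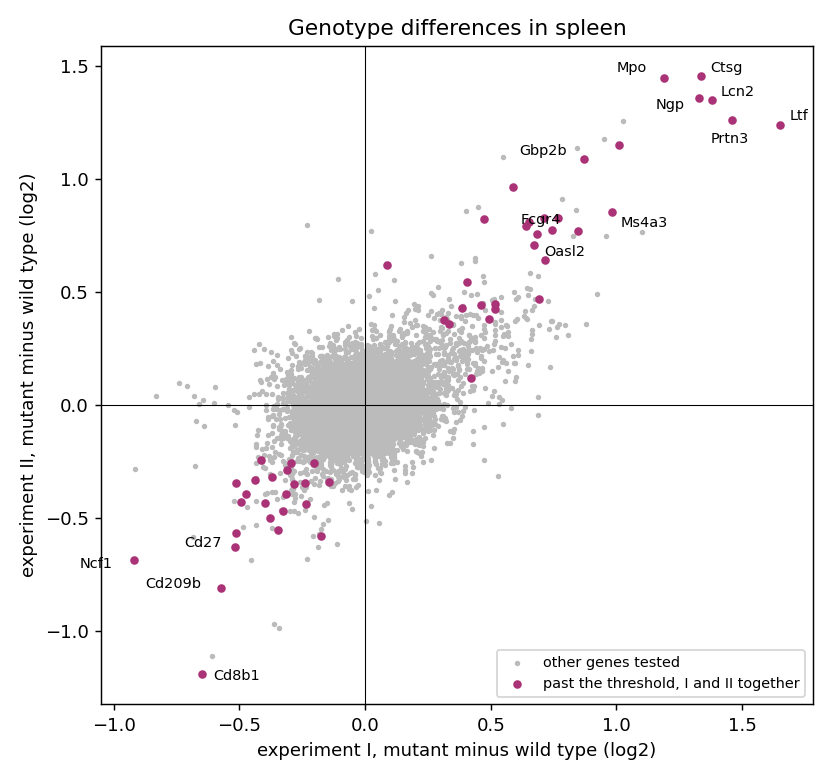
Mutant minus wild type difference of each gene tested in spleen (log2) in experiment I (horizontal axis) and experiment II (vertical axis); each point is a gene and the 55 genes past the threshold are drawn larger. Called genes run from Cd8b1 and Ncf1 at the lower left to Ltf and Ctsg at the upper right.

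The lists in spleen followed these genes. All 17 measured neutrophil markers were higher, by 0.89 on average and in 12 of 12 mutant arrays; 8 passed over all genes and 13 when adjusted over the list alone (camera adjusted p = 1.5e-25, adjusted p = 0.016 with an estimated correlation, permutation p = 8.0e-04 before and 0.0080 after adjustment). All 14 T cell markers were lower, by -0.40 on average and in 12 of 12 arrays; 3 passed over all genes and 13 when adjusted over the list alone (camera adjusted p = 2.7e-22, adjusted p = 1.3e-04 with an estimated correlation, permutation p = 3.0e-05 before and 6.0e-04 after adjustment). Of 17 interferon gamma response genes 15 were higher, by 0.26 on average and in 11 of 12 arrays; 4 passed over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.1e-14, adjusted p = 0.0029 with an estimated correlation, permutation p = 0.0017 before and 0.0085 after adjustment). These 3 lists also passed fry. Of 32 type I interferon genes 30 were higher, by 0.17 on average and in 12 of 12 arrays; 1 passed over all genes and 1 when adjusted over the list alone. That list passed camera (adjusted p = 9.5e-08), but had an adjusted p = 0.17 with an estimated correlation and a permutation p of 0.0014 before and 0.0085 after adjustment over 20 lists. In single experiments its mean was 0.26 in experiment I (camera adjusted p = 3.2e-09, adjusted p = 0.13 with an estimated correlation) and 0.089 in experiment II (camera adjusted p = 0.033, adjusted p = 0.61 with an estimated correlation). The experiments differed by -0.17 in this mean (camera adjusted p = 0.0067, adjusted p = 0.77 with an estimated correlation).

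Erythroid and cell cycle genes averaged higher in mutant spleen. Over 20 other settings the erythroid mean ran from 0.30 to 0.49 and the cell cycle mean from 0.15 to 0.44. Each list kept its call in 15 of these settings. All 12 erythroid markers were higher, by 0.46 on average and in 12 of 12 arrays, with 0 past limma's threshold over all genes and 1 when adjusted over the list alone (camera adjusted p = 9.5e-08). All 13 cell cycle genes were higher, by 0.40 on average and in 12 of 12 arrays, with 0 past it over all genes and 10 when adjusted over the list alone (camera adjusted p = 2.8e-11). Both calls were lost with an estimated correlation (adjusted p = 0.17 for the erythroid and 0.13 for the cell cycle list), while both lists passed the permutation test of array means (adjusted p = 0.015 and 0.024). Gata1, the erythroid transcription factor, read 0.43 ± 0.12 SE (adjusted p = 0.11), and Top2a, a topoisomerase of dividing cells, 0.59 ± 0.17 SE (adjusted p = 0.13). Immediate early and heat shock genes averaged -0.33 with 0 of 11 members higher, 0 past the threshold over all genes and 0 when adjusted over the list alone, and camera adjusted p = 5.1e-04 (adjusted p = 0.17 with an estimated correlation).

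The phagocyte oxidase list averaged -0.19 and passed camera (adjusted p = 0.014), but had an adjusted p = 0.17 with an estimated correlation. Ncf1 was the 1 member that passed, over all genes and when adjusted over the list alone. With 6 measured members and Ncf1 at -0.80, the list mean may largely restate that gene. NK cell markers averaged -0.11 (camera adjusted p = 0.020) and platelet markers 0.15 (camera adjusted p = 0.0056), each with adjusted p = 0.25 with an estimated correlation. Dendritic cell markers averaged -0.15 (camera adjusted p = 0.089, permutation adjusted p = 0.026), with Cox6a2 past the threshold over all genes, 2 members when adjusted over the list alone, and Siglech, a marker of plasmacytoid cells, at -0.63 ± 0.20 SE (adjusted p = 0.21). The remaining means in spleen were -0.12 for B cell markers (camera adjusted p = 0.089), -0.048 for plasma cell markers (0.47), 0.074 for monocyte and macrophage markers (0.11), 0.076 for antioxidant genes (0.11), 0.0067 for inflammatory cytokines (0.65), 0.028 for globin genes (0.52), -0.29 for exocrine pancreas genes (0.11), -0.031 for ribosomal proteins (0.51) and -0.066 for genes near Ncf1 on chromosome 5 (0.11).

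**Figure D4:**
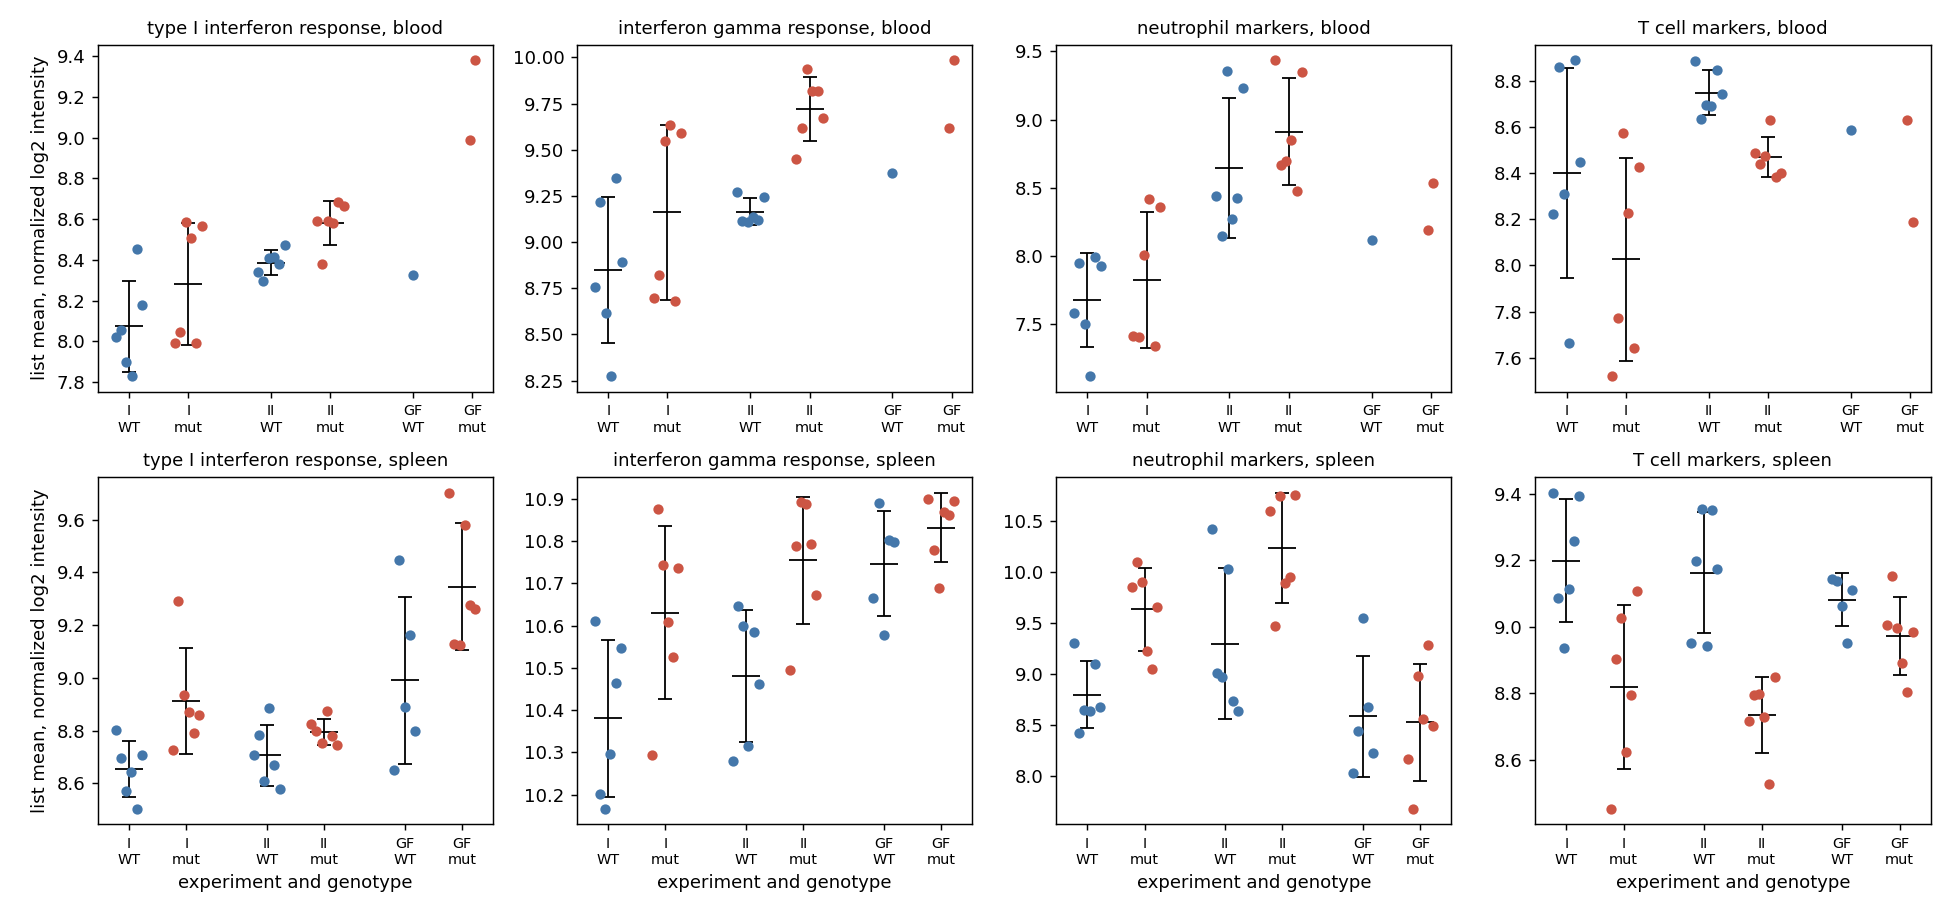
Mean normalized log2 intensity of 4 gene lists (vertical axes) on each array, by experiment and genotype (WT, wild type; mut, mutant; GF, germ-free), with blood above and spleen below. Points are arrays and black lines the mean ± SD of groups of 5 or 6; in spleen of experiments I and II all 12 mutant arrays lie above their wild type mean for the neutrophil list and below it for the T cell list.

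The germ-free comparison asked whether the genotype differences are seen in spleen of mice without microbes. Ncf1 was the 1 gene of 8968 that passed limma's test, and 91 genes had an unadjusted p under 0.05 where chance gives 448.4. The fit shares its spread with the other spleen arrays, so its p values do not measure the germ-free spread alone. Array weights in spleen ran from 0.148 in experiment I to 5.08 in germ-free mice. With only the germ-free arrays in the fit, 0 genes passed. Interferon-inducible genes had the next smallest p without passing. Oas2 read 1.04 ± 0.25 SE (adjusted p = 0.75), Oas1g 0.89 ± 0.22 SE (adjusted p = 0.75), Usp18, a brake on interferon signalling, 0.74 ± 0.23 SE (adjusted p = 1.00) and Helz2 0.40 ± 0.12 SE (adjusted p = 1.00), each higher in 6 of 6 mutant arrays. Of 32 type I interferon genes 31 were higher, by 0.36 on average and in 6 of 6 mutant arrays, with 0 past the threshold over all genes and 3 when adjusted over the list alone. The list passed camera (adjusted p = 1.4e-35, adjusted p = 0.0011 with an estimated correlation), while fry gave adjusted p = 0.091 and an exact permutation test of the 11 array means p = 0.061 before and 0.34 after adjustment. Without the 3 spleen arrays that carry pancreas genes, of which wild type replicates GF-S1 (11.21) and GF-S1141 (9.16) are germ-free, the mean of the type I interferon list in germ-free spleen was 0.18 ± 0.18 SE of the array means. It passed camera at the preset correlation (adjusted p = 2.2e-07) and lost its call with an estimated correlation (adjusted p = 0.32) and with fry (adjusted p = 0.76). Ncf1 did not pass without these arrays. Without wild type replicate GF-S461 Oas1g passed (adjusted p = 0.0090).

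The exocrine pancreas list averaged -1.60 in germ-free spleen, with 12 members lower when adjusted over the list alone and 0 past limma's threshold over all genes (camera adjusted p = 1.8e-30, adjusted p = 0.011 with an estimated correlation, 0.27 with fry and 0.34 by permutation); the enzyme genes Amy2a5 (-2.10) and Cela1 (-1.32) read lower in 6 of 6 arrays. The mean was -0.065 without the pancreas-bearing arrays. The interferon gamma (0.085), plasma cell (0.13), T cell (-0.11), erythroid (-0.24) and phagocyte oxidase (-0.14) lists passed camera with adjusted p of 0.0028 to 0.019. None of these 5 kept its call, with adjusted p = 0.30 to 0.80 with an estimated correlation. Ncf1 was the 1 oxidase member that passed when adjusted over the list alone, and 0 members of the other 4 lists did. With 6 measured oxidase members and Ncf1 at -0.92, that list mean may largely restate Ncf1. Neutrophil markers averaged -0.058 (camera adjusted p = 0.73). The mean and median differed in sign for the inflammatory cytokine, macrophage, NK and platelet lists, none of which passed.

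Of the 55 genes called in conventional spleen, 39 had the same sign in germ-free spleen and 2 an unadjusted p under 0.05. Their median size was 0.475 in conventional and 0.056 in germ-free mice in the same direction. Ltf read -0.19 ± 0.47 SE, Ctsg -0.094 ± 0.33 SE, Cd8b1 -0.20 ± 0.13 SE, Cd27 -0.025 ± 0.12 SE and Oasl2 0.70 ± 0.26 SE in germ-free spleen. The difference itself was tested as an interaction, which 0 genes passed with limma (208 at an unadjusted p under 0.05, where chance gives 448.4). Cd8b1 (0.72 ± 0.16 SE, adjusted p = 0.79) and Ctsg (-1.49 ± 0.40 SE, adjusted p = 1.00) were among its smallest p values. T cell markers differed by 0.29 on average with 1 member past the threshold when adjusted over the list alone; the list passed camera (adjusted p = 8.8e-09, adjusted p = 0.049 with an estimated correlation) but not fry (adjusted p = 0.21). The neutrophil list difference of -0.95, with 8 members lower when adjusted over the list alone, lost its call, with adjusted p = 0.099 with an estimated correlation. The type I interferon list difference of 0.18 lost its call too, with adjusted p = 0.28 with an estimated correlation, as did the interferon gamma list, which went the other way by -0.18 with 1 of 17 members positive (camera adjusted p = 5.8e-05, adjusted p = 0.20 with an estimated correlation). The erythroid (-0.70), cell cycle (-0.33), exocrine pancreas (-1.31), plasma cell (0.18) and platelet (-0.15) lists and the genes near Ncf1 (0.11) passed camera and had adjusted p = 0.20 to 0.34 with an estimated correlation. No list passed fry in this comparison. Germ-free state and experiment cannot be told apart here. With array weights 1719 genes passed the interaction. Those weights favoured high-number wild types and low-number mutants in experiment I, so this count cannot be told apart from the number range.

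Each experiment was also compared alone. In blood of experiment I, Gvin1 (1.64 ± 0.23 SE, adjusted p = 0.0019) and Oasl2 (1.36 ± 0.24 SE, adjusted p = 0.038) rose in 6 of 6 arrays; in experiment II, Gvin1 (1.91 ± 0.23 SE, adjusted p = 1.4e-04) and Ffar2 (1.16 ± 0.15 SE, adjusted p = 2.7e-04) did. In spleen of experiment I, 6 genes passed, with Ms4a3 (0.98), Fcgr4 (0.85) and the guanylate-binding protein gene Gbp7 (0.52) higher, and Ncf1 (-0.92), Cd8b1 (-0.65) and Sun2 (-0.52), of the nuclear envelope, lower, with adjusted p from 0.0071 to 0.044. In spleen of experiment II, 7 genes passed. Gbp2b (1.09), the mast cell protease Prss34 (0.82), Itgb2l (0.81) and Ffar2 (0.62) were higher, and Cd8b1 (-1.19, adjusted p = 7.6e-07), Cd27 (-0.63) and Tdrp (-0.55) lower. The genotype difference of no gene passed a test of experiment II against I with limma. At an unadjusted p under 0.05 there were 145 genes in blood and 203 in spleen, where chance gives 453.75 and 448.4. Both counts lie below chance, so the lack of calls does not show that the experiments agree. Ffar2 differed by 1.03 ± 0.21 SE in blood (adjusted p = 0.55). With array weights 3324 genes passed in spleen, a count that cannot be told apart from the number range of experiment I. The counts of these single comparisons rest on few arrays and on a spread shared with the other experiments. With only the arrays compared in the fit they became 0 in blood and spleen of experiment I and 45 in blood of experiment II. With median centring they became 0 in blood and 1 in spleen of experiment I and 2 in spleen of experiment II. Other settings raised them: with the range of the title numbers as a block 21 genes passed in spleen of experiment I and 44 in spleen of experiment II, and with array weights 4557 and 38, and 125 in blood of experiment II. The weights in spleen of experiment I favoured high-number wild types and low-number mutants, so the 4557 genes cannot be told apart from the number range. Leaving out single arrays gave 1 to 6 genes in blood and 1 to 11 in spleen of experiment I. Oasl2 in blood of experiment I kept its call in 10 of 27 such fits (adjusted p up to 0.15) and in 8 of 14 other settings. Of 35 such fits for spleen of experiment I, Sun2 kept its call in 12, Fcgr4 in 26, Ms4a3 and Cd8b1 in 27 and Gbp7 in 33, and in other settings Sun2 and Ms4a3 kept theirs in 7 (of 14 and 13). Without mutant replicate 25, which stood apart for it, Sun2 read -0.39 (adjusted p = 0.087). Among the calls in spleen of experiment II, Itgb2l kept its call in 22 of 35 fits, Gbp2b in 28 and Ffar2 in 32, and in 6, 7 and 13 other settings (of 13, 13 and 14).

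The genotype difference was compared between the tissues in experiments I and II. Ctsg and Ms4a3 passed among 9064 genes, with spleen minus blood differences of 1.34 ± 0.23 SE (adjusted p = 0.0040) and 0.65 ± 0.12 SE (adjusted p = 0.0070). At an unadjusted p under 0.05 there were 367 genes, where chance gives 453.2. Gvin1 read -0.86 ± 0.20 SE (adjusted p = 0.22) and Mpo 1.38 ± 0.33 SE (adjusted p = 0.22). Ctsg, Ms4a3 and Mpo did not pass the filter in blood, where their group means were 5.97 to 6.13, so a genotype difference could hardly appear there and these values mostly restate the spleen differences. Erythroid (0.62), cell cycle (0.49) and neutrophil (0.73) lists differed, with adjusted p = 0.017, 0.018 and 0.043 with an estimated correlation, and 11, 5 and 8 of their members were higher in that difference when adjusted over the list alone. With fry the adjusted p was 0.021, 0.021 and 0.054, so the neutrophil list did not pass that test. Without the members that did not pass the filter in blood, a setting chosen after the data were seen, 15 neutrophil, 12 erythroid and 9 cell cycle genes were left, with differences of 0.64, 0.62 and 0.56. The neutrophil call was then lost with an estimated correlation (adjusted p = 0.099) and with fry (0.13), and the other lists passed both (adjusted p = 0.012 and 0.016 for each). The interferon gamma list difference of -0.13 had a camera adjusted p = 0.033 and an adjusted p = 0.65 with an estimated correlation. No gene passed with the upper 25% of probes or with median centring, where the median of all genes shifted by -0.14, and 16 genes passed with array weights.

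The comparison of germ-free against conventional wild type spleen asked which transcripts differ without microbes, and 3679 genes passed limma's test, 1737 higher and 1942 lower. Ncf1 rose by 1.02 ± 0.14 SE (2.03-fold, adjusted p = 9.4e-07). Its rise depended on the scaling too and ran from 0.87 to 1.63 over 11 other settings. The largest rises were in Uqcrb (2.16), of the respiratory chain, Nop10 (2.15) and Zbtb7a (1.90), and the largest falls in Chmp4b (-3.50), Raly (-3.33), Ap2b1 (-2.90) and Clec2d (-2.72). Germ-free mice formed an experiment of their own, and wild type spleen of experiment II differed from that of experiment I in 4225 genes. The 2 sets shared 1664 genes, where 1733 would follow from independence. Equal array numbers in experiments I and II leave the errors of the 2 differences uncorrelated, so this overlap does not tell germ-free state from experiment. The split of higher and lower genes depended on the scaling, with 4350 higher and 492 lower with median centring, where the median of all genes shifted by 0.34, and 6005 higher and 318 lower with each experiment normalized on its own, where it shifted by 0.46. The deposited values gave 3794 higher and 894 lower at a shift of 0.20, and the count was 5777 with array weights and 2222 with the upper 25% of probes.

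Germ-free blood held 2 mutant arrays and 1 wild type array, too few for a test. Oasl2 read 10.37 and 10.81 in the mutants and 7.70 in the wild type, Usp18 8.75 and 9.71 against 7.44, Irf7, a regulator of interferon genes, 9.83 and 11.35 against 8.81, and Gvin1 10.25 and 10.94 against 9.17. The type I interferon list mean was 8.99 and 9.38 against 8.33, a difference of 0.86 that became 0.51 with median centring. Ncf1 read 7.20 and 6.56 against 7.62.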

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

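The tests of liver genes, of the neutrophil and T cell genes, of the type I interferon list, of list members that passed the filter in blood and of splits within number ranges were chosen only after the data were seen; the other split counts were set beforehand. Of 304 groups of values tested for a stray sample 9 had one, where chance at about 1 in 20 gives 15.2.

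In single genes, Ffar2 read 6.73 in wild type replicate 5 of blood I against 6.06 to 6.17 in the others of its group. Cd8b1 read 11.62 in wild type replicate 8 of blood II against 11.13 to 11.19. Ngp read 9.22 in mutant replicate 27 of spleen I against 10.21 to 10.78. Mutant replicate 25 of spleen I stood apart for Top2a (11.06 against 9.73 to 10.03) and Sun2 (9.84 against 10.58 to 10.73). The type I interferon list mean was 8.38 in mutant replicate 34 of blood II against 8.58 to 8.68, and 9.29 in mutant replicate 6 of spleen I against 8.73 to 8.94. The exocrine pancreas list mean was 10.68 in wild type replicate 7 of spleen I against 6.36 to 6.63, and 6.73 in mutant replicate 3 of germ-free spleen against 6.26 to 6.30.

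A test of the difference itself called a genotype difference between tissues for Ctsg (1.34), Ms4a3 (0.65), neutrophil markers (0.73), erythroid markers (0.62) and cell cycle genes (0.49), each spleen minus blood, and between germ-free and conventional spleen for T cell markers (0.29). Ctsg and Ms4a3 did not pass the filter in blood, so their values do not show that genotype acts differently there, and the neutrophil call was lost without the members of that kind (adjusted p = 0.099 with an estimated correlation). The T cell call is near its threshold, with adjusted p = 0.049 with an estimated correlation, and was not made by fry (adjusted p = 0.21), nor was that of the neutrophil markers (adjusted p = 0.054). Outside the tested comparisons, the type I interferon list was 0.86 higher in the 2 mutant arrays of germ-free blood than in the wild type array, and 3 probes without a gene name passed the threshold in blood and 4 in spleen of experiments I and II.

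The mean of 16 liver genes followed the first component of the blood arrays among the 12 arrays of experiment I. The component held 64.8% of the variance, and the mean correlated with it at r = -0.985 and rho = -0.993 (permutation p = 1e-05 for both, the smallest the draws can give, 2e-05 after adjustment over the 2 relations tested), and at r = -0.973 without the 2 farthest arrays; the 16 genes had been picked from outside the 50 leading genes of the component. Blood of experiment II stood at the floor, so the relation is within 1 experiment. The list was written after the data were seen and the component is drawn from the same arrays, so the relation is no independent test. The liver mean did not follow array brightness (r = 0.103, rho = -0.084, permutation p = 0.80 before and after adjustment; r = -0.132 without the 2 farthest), which argues against dim arrays. It was 0.73 higher in mutants with an exact permutation p of 0.266, and 3 wild type arrays lay above the median mutant array, which argues against genotype alone as the source. RNA of another tissue in these samples may be the source.

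Neutrophil genes were higher and T cell genes lower in mutant spleen of experiments I and II. More blood left in mutant spleens could not raise genes that read lower in blood than in spleen. In both experiments 7 neutrophil markers had a lower mean in mutant blood than wild type spleen (Camp, Ngp, Ltf, Mpo, Elane, Prtn3 and Ctsg). As a set they read -1.58 ± 0.178 SE (experiment I) and -2.14 ± 0.362 SE (experiment II) in blood relative to spleen. The sign of these values is fixed by that choice of genes. Yet the 7 genes rose by 1.29 ± 0.248 SE in mutant spleen, which argues against blood as their source. The other 10 members rose by 0.608 ± 0.203 SE, and each had a higher mean in blood than in spleen in at least 1 experiment. As a set, blood left in the spleen and a change of the spleen itself cannot be told apart for them. Their rise was uneven. In experiment II Csf3r and Cxcr2 read 9.57 and 9.08 in mutant blood, yet 7.28 and 6.95 in mutant spleen against 7.08 and 6.81 in wild type. There S100a9 read 12.76 in mutant blood, and 12.32 in mutant spleen against 10.98 in wild type. In experiment I S100a9 read higher in mutant spleen (11.64) than in mutant blood (11), which added blood alone would not give. Lcn2 did so in both experiments (10.07 against 9.227, and 11.07 against 10.47). Mmp9 and Retnlg read lower in mutant spleen than in mutant blood in both. These means are given without their spread, so single genes do not decide between the 2 for the set. A lack of T cells alone would raise the other cell types alike, yet the neutrophil list stood 1.01 ± 0.255 SE above the B cell list, which read -0.123. Without the arrays that carry pancreas genes the neutrophil difference was 0.877 ± 0.226 SE against 0.887 with them, and 0.939 ± 0.374 SE in experiment II, which has no such array. For these 7 genes more cells that make granule transcripts in mutant spleen is thus a candidate explanation, found and tested on the same data, and differences in how spleens were dissected were not tested.

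The type I interferon list averaged higher in mutant spleen, by 0.17 in experiments I and II and by 0.36 in germ-free mice, and passed camera at the preset correlation but not fry (adjusted p = 0.12 and 0.091), and with an estimated correlation only in germ-free mice (adjusted p = 0.17 and 0.0011). By permutation of array means it passed in experiments I and II together, but not in germ-free mice. In experiment I the difference was 0.159 ± 0.0555 SE in the high number range and 0.358 ± 0.160 SE in the low one. Each range held 3 mutant and 3 wild type arrays, and the low one included mutant replicate 6, which stood apart for this list. A higher mutant mean in both ranges argues, on these few arrays, against 1 range of animals as the whole source. In germ-free spleen the difference was 0.178 ± 0.179 SE without the arrays that carry pancreas genes, with 3 wild type arrays left, against 0.36 with them. Pancreas on wild type arrays and genotype cannot be told apart for the germ-free part, since too few arrays remain. The germ-free part therefore may rest on those arrays.

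Other splits of the samples were fitted in the same way, 100 for each comparison with the real one included. Each share was read at 0.05 on its own, without adjustment over the comparisons. In blood of experiments I and II, 3 splits gave as many genes as the real 8 (highest other 52), in blood of experiment II 1 gave as many as 2 (highest other 0), in spleen of experiment II 3 gave as many as 7 (highest other 182), in germ-free spleen 4 gave as many as 1 (highest other 54), between tissues 3 gave as many as 2 (highest other 36), and for germ-free against conventional wild types 1 gave as many as 3679 (highest other 2317). The share was under 0.05 for these. The germ-free count is 1 gene, whose call was lost with only the germ-free arrays in the fit. The 2 genes between tissues did not pass the filter in blood. The wild type splits moved arrays between experiments, so their share cannot separate germ-free state from experiment. Chance is not excluded for spleen of experiments I and II, where 11 splits gave as many as 55 (highest other 2243), for blood of experiment I (21 splits, real 2, highest other 1642) or for spleen of experiment I (19 splits, real 6, highest other 3847). All 100 splits gave at least the 0 genes of the interactions by experiment in blood (highest other 66) and spleen (2322) and by germ-free state (29). Splits that called many more genes than the real one point to a structure of the samples. In spleen of experiment I the range of the title numbers is such a structure, with 5022 genes between ranges and 0 in spleen of experiment II. Splits were also drawn within ranges, with the range as a block. In spleen of experiments I and II only the real split, with 207 genes, was as large (highest other 109). The share was under 0.05 there and in spleen of experiment II (2 splits, real 44, highest other 198). So it was in blood of experiment II (1 split, real 2, highest other 0). The block was chosen after the range was seen, and the splits set beforehand did not exclude chance for spleen of experiments I and II. The share is thus under 0.05 there only with that block. Chance is not excluded with that block in spleen of experiment I, where 7 splits gave as many as 21 (highest other 539), in blood of experiment I (22 splits, real 1, highest other 3404) or in blood of experiments I and II, where 6 splits gave as many as 8 (highest other 1827).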

How the results depend on the processing

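The number range block, the liver covariate, the fits without doubted arrays, alone and with other list tests, and the upper 25% of probes were chosen only after the data were seen. No gene, list or germ-free blood value reversed, and no uncalled value changed sign. Counts were not judged by sign, and the balance of higher and lower genes in germ-free against conventional wild type spleen turned with the scaling. Apart from fits that leave out 1 array, 1160 gene values kept their side of the threshold, 105 became weaker and 41 stronger, and of list values 220 kept it and 35 became weaker. When single arrays were left out, 2962 gene values kept it, 213 became weaker and 13 stronger, and for lists 416 and 7. Signal over background limits all of this: the 75th percentile of blood arrays was at most 3.06 times the 5th. The filter on detection p and a slide block were not run, since no detection p or slide is given. The cause was not tested for the changes below, unless stated. Counts are given in the order blood I and II, spleen I and II, germ-free spleen, blood I, blood II, spleen I, spleen II (main 8, 55, 1, 2, 2, 6 and 7), where they moved. Median centring gave 20 in spleen I and II, 0 in germ-free spleen, 0 in blood I, 1 in spleen I, 2 in spleen II, 0 genes by tissue (main 2), and 0.51 in germ-free blood (main 0.86); it shifted the median of all genes by 0.11 in blood II and -0.15 in spleen I. Each experiment normalized on its own gave 1 in blood I, 13 in blood II, 1 gene by experiment in blood (main 0), 6 by tissue and 6323 for germ-free against conventional wild type spleen (main 3679). The deposited values gave 11 in spleen II and 5 by tissue. Without a filter there were 1 in blood I and 2 in spleen I, and with all probes 13 in blood I and II, 4 in blood II and 10 in spleen I. Array weights, which ran from 0.148 to 5.08, gave 58, 3182, 13, 125 (blood II), 4557 (spleen I) and 38 (spleen II), 3324 by experiment in spleen, 1719 by germ-free state, 16 by tissue, 5777 for germ-free against conventional and 12 other lists (main 19). In spleen I these weights favoured high-number wild types and low-number mutants. The counts of 3182, 4557, 3324 and 1719 therefore cannot be told apart from the number range. Only the arrays compared gave 0 in germ-free spleen, 0 in blood I, 45 in blood II and 0 in spleen I. The range block gave 207 in spleen I and II, 1 in blood I, 21 in spleen I and 44 in spleen II; with only the arrays compared as well it gave 186, 0 in germ-free spleen, 0 in blood I, 60 in blood II, 30 in spleen I and 14 in spleen II. The liver covariate gave 27 in blood I and II and 5 in blood II, and without the blood arrays of experiment I both gave 29, since only experiment II is left. Without the 3 spleen arrays with pancreas genes there were 41 in spleen I and II, 0 in germ-free spleen and 2 in spleen I; there the type I interferon list, at 0.179 in spleen I and II and 0.178 in germ-free spleen, had adjusted p = 0.111 and 0.317 with an estimated correlation and 0.104 and 0.756 with fry, of which only the estimated correlation in germ-free spleen passed with these arrays (0.00106). The upper 25% of probes, with fewer genes tested, gave 4, 33, 0, 1 in blood II, 3 in spleen I, 3 in spleen II, 0 by tissue and 2222 for germ-free against conventional. Other list tests leave the means of the type I interferon list, 0.20 in blood, 0.17 in spleen and 0.36 in germ-free spleen, as they are. Its adjusted p was 0.197 and 0.170 with an estimated correlation in blood and spleen, and 0.166, 0.116 and 0.0911 with fry. Of the other lists 5 passed with an estimated correlation and 4 with fry. Over all settings the type I mean ran from 0.17 to 0.35 in blood, 0.12 to 0.22 in spleen and 0.18 to 0.41 in germ-free spleen. By tissue, the number in the title as a replicate block gave 2 genes and differences within a number 3; the 24 same-numbered pairs correlated at -0.194 to 0.619 (median 0.146). Leaving out each array gave 6 to 13 in blood I and II (13 without wild type replicate 30 of blood I), 36 to 71 in spleen I and II, 0 to 1 in germ-free spleen, 1 to 6 in blood I, 2 to 4 in blood II, 1 to 11 in spleen I, 4 to 16 in spleen II, 0 to 0 by experiment and by germ-free state, 2 to 3 by tissue, 3112 to 3973 for germ-free against conventional, 0.17 to 0.24, 0.14 to 0.19 and 0.27 to 0.47 for the type I list, and 0.67 to 1.06 in germ-free blood.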

Other observations

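The tests named here were chosen only after the result was seen. In spleen of experiment I the arrays with title numbers up to 20 differed from those above in several gene groups, independent of genotype. B cell markers averaged 0.77 higher in the low range (8 members called higher, 1 lower; camera adjusted p = 0.0045), monocyte and macrophage markers 0.59 higher (8 called higher, 0 lower; adjusted p = 0.013), and cell cycle genes -0.65 (8 called lower, 0 higher; adjusted p = 0.017). With an estimated correlation the adjusted p was 0.37, 0.37 and 0.70. The labels do not say what the numbers stand for.

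In germ-free blood the platelet list read 10.20 and 10.03 in the mutants and 10.98 in the wild type, and the macrophage list 7.55 and 8.74 against 7.77. Irgm2 read 9.20 and 9.59 against 8.08, Tdrp 7.70 and 7.52 against 8.01, and Ffar2 6.47 and 6.51 against 6.53. Second probes were measured for 13 of the genes called in spleen of experiments I and II; these 16 probes had 0 opposite signs.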
